A study of Mus musculus with 6 samples.

How the data were processed

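The deposited count matrices, as made by the authors, hold raw UMI counts for 31053 genes, and per the submitters' processing notes they came from Cell Ranger 9.0.0 with the mm10 reference. Tumours were digested with collagenase, strained and captured as single cells, and the libraries were read on a Singular G4 sequencer per the labels. Library 1 of each group was made with the v3 chemistry and libraries 2 and 3 with the v4 4-plex chemistry. Groups, main tests, gene lists, marker lists and some of the alternatives were fixed before the data were examined. Other alternatives were chosen after the data were seen, among them removing the highest 5% of doublet scores and leaving out or adding single clusters. Some further tests were also chosen then, and these are named below. Because chemistry separates library 1 from the others and saline 1 counts were not used here, all tests used saline 2 and 3 and VIVIT 2 and 3, with all 5 libraries as an alternative. The libraries had 0 shared barcodes. Pairs of libraries differed by a chi-square per degree of freedom from 31.7 (VIVIT 2 and 3) to 412 (VIVIT 1 and 2), so none repeats another.

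Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs. Scrublet called 21 of 10443 cells (0.201%), below the 0.5% at which such a run counts as working, so doublet calling has not worked here. The called cells were removed, and removing the highest 5% of doublet scores in each library was added as an alternative. Counts were normalised, log transformed and reduced to 2000 variable genes and 30 principal components, with 15 neighbours and Leiden clustering at resolution 1 (0.5 as an alternative) over the 5 libraries without integration. Clusters took the name of the marker list with the most markers, at least 3, each 1.5-fold higher than elsewhere and found in 10% of cells. A cluster stayed unnamed where marker lists tied, where its 10 leading genes held more markers of another class, or where they were cartilage or skeletal muscle genes. It also stayed unnamed where its median depth was under 0.333 of that of its libraries and none of its leading genes was a marker of its class.

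Counts were summed per library and class. A class was tested for genes where each of the 4 libraries had at least 20 cells, which left fibroblast-like, epithelial-like, phagocyte-like and endothelial-like cells and the sum of all cells. Neutrophil-like, T/NK, dendritic, B and pericyte-like cells were left out of the 4-library gene tests because a library held fewer than 20 of them. After the data were seen, edgeR was also run on T/NK, neutrophil-like and dendritic cells with saline 2 as the only saline library. Genes were filtered with filterByExpr, scaled by TMM and tested by the quasi-likelihood F test of edgeR, with Benjamini-Hochberg adjustment and a limit of 0.05. Log2 ratios are VIVIT over saline. Alternatives tried were RLE factors, DESeq2, no filter on low counts, all 5 libraries, a block for the replicate number, leaving out each library, at most 10% mitochondrial UMIs, doublets kept and Leiden resolution 0.5.

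Gene lists (35) and marker lists (17) with at least 5 tested members were tested by camera on voom values with a preset correlation of 0.01. Fry and camera with an estimated correlation were run beside it. Each list's own genes were also adjusted over that list alone. Class shares were tested by edgeR with the number of kept cells as offset and by exact permutation of the library labels. The difference between the fibroblast-like and phagocyte-like effects was tested by limma on within-library differences of log CPM with a prior count of 1.

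Genes named in the text followed a rule. Where fewer than 3 genes passed, the 5 higher and 5 lower genes with the smallest p were taken, with no limit on their counts. Unnamed, immunoglobulin and T-cell receptor variable genes were passed over. Up to 4 members with the smallest p were taken for each called list, and NFAT family genes and Rcan1 were always taken. Fibroblast-like cells also always had Il6, Cxcl1, Ccl2, Cxcl12, Acta2, Col1a1 and Postn.

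Simulated counts with the real depth of the libraries were run through the same tests. In fibroblast-like cells 3% of genes changed 2-fold and 82% of genes changed 8-fold were found, with 13 false calls among 12586 genes. In epithelial-like cells these were 7% and 92%, with 11 false calls among 12811. In phagocyte-like cells they were 4% and 100%, with 10 false calls among 11616. All 5 of 5 shifted lists were called in each, and 0, 1 and 0 of 25 unshifted lists. Each gene was drawn independently of the others, so these list counts do not cover lists whose genes vary together. In the real fibroblast-like cells the myofibroblastic list had an estimated correlation of 0.46. There, splits that mix saline and VIVIT called 11 and 9 of 32 lists. A class simulated with 6-fold more cells, before shares were rescaled to their total, was fitted at log2 1.78, below the simulated size. Its adjusted p was 0.00102 by edgeR, with 0 of 7 unchanged classes called. Simulated shares varied less between libraries than some real saline ones, such as neutrophil-like cells at 15.3% and 0.818%. The result does not carry over to such classes.

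Software was Python 3.11.15 with scanpy 1.11.5, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Gene coordinates are those of GENCODE vM21 on GRCm38.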

Results

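Orthotopic pancreatic tumours were grown in mice from KPC cells, a pancreatic ductal adenocarcinoma line. They were injected in place with saline or with VIVIT, a peptide that blocks the docking of calcineurin on NFAT transcription factors. Every library had 2 weeks before injection and 2 weeks from injection to harvest, so all values describe the tumours at harvest. The deposited single-cell libraries number 3 per group by their labels. Libraries 2 and 3 of each group were made with the v4 chemistry and library 1 of each group with the v3 chemistry. Saline 1 has 22801 barcodes but its counts were not analysed here. The tests therefore compare saline 2 and 3 with VIVIT 2 and 3 (n = 2 and 2), and VIVIT 1 enters only where it is said to be added. Whether each library came from a separate animal is not stated, so every p-value here measures only the spread between these samples, which may be technical.

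Sequencing gave 34.8 and 14.5 M UMIs in saline 2 and 3, 49.6 and 34.7 M in VIVIT 2 and 3, and 36.8 M in VIVIT 1. Saline 3 was the weakest library, with 46.1% of its barcodes above 20% mitochondrial UMIs against 14.8% in saline 2, 21.3% and 13.05% in VIVIT 2 and 3, and 21.6% in VIVIT 1. It kept 611 cells, against 1912 in saline 2, 2849 and 2032 in VIVIT 2 and 3, and 3018 in VIVIT 1. Median UMIs per kept cell were 7552 and 8024 in saline, 7956 and 8190.5 in VIVIT 2 and 3, and 4267.5 in VIVIT 1. The 10422 kept cells formed 28 clusters, named by marker genes as fibroblast-like, epithelial-like, mononuclear phagocyte-like, endothelial-like, neutrophil-like, T/NK lymphocyte-like, dendritic, B, pericyte-like and smaller classes.

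Which cell types change in share when NFAT docking is blocked? T/NK lymphocytes, the class that carries T-cell receptor genes and in which NFAT drives activation, made up more of the cells in every VIVIT library than in either saline library. Epithelial-like cells, the class expected to hold the grafted tumour, and fibroblast-like cells were scarcer in VIVIT 2 and 3. None of these differences passed a test, and the saline libraries lay far apart.

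T/NK lymphocytes were 4.55% (95% interval 3.66 to 5.58) and 1.15% (0.462 to 2.35) of cells in saline 2 and 3, and 14.99% (13.7 to 16.4) and 13.5% (12.1 to 15.1) in VIVIT 2 and 3. The group values were 2.85 ± 2.41% (n = 2) and 14.3 ± 1.03% (n = 2), with 7.69% (6.76 to 8.70) in VIVIT 1. These intervals are exact Clopper-Pearson intervals that cover counting error only. The fitted T/NK log2 ratio was 2.30 (SE 1.14), adjusted p = 0.635 by edgeR. An exact permutation of the labels gave p = 0.333, the smallest value that 2 against 2 libraries can reach, and 0.2 with VIVIT 1 added, where the floor is 0.1.

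Epithelial-like cells were 14.96% and 31.6% in saline against 7.65% and 7.78% in VIVIT 2 and 3 (log2 −1.59, SE 1.05), but 22.6% in VIVIT 1. Fibroblast-like cells were 7.79% and 25.9% in saline against 6.002% and 5.81% (log2 −1.51, SE 1.09), and 19.5% in VIVIT 1. Without saline 3 the fibroblast-like log2 was −0.40, without saline 2 it was −2.13, and with VIVIT 1 added −0.68. Dendritic cells were 4.24% and 0.491% against 4.67% and 6.59% (log2 1.21, SE 1.21). All these had the same edgeR adjusted p = 0.635 as B cells (log2 1.68, SE 1.54) and pericyte-like cells (log2 −1.30, SE 1.30). B cells turned to log2 −2.46 without VIVIT 2 and pericyte-like cells to 1.45 without saline 3. Endothelial-like cells were 4.24% and 4.26% in saline, 6.35% and 4.87% in VIVIT 2 and 3, and 8.22% in VIVIT 1 (log2 0.40, edgeR adjusted p = 0.908). Phagocyte-like cells were 38.4% and 19.3% against 32.4% and 41.0% (log2 0.34, edgeR adjusted p = 0.908). Neutrophil-like cells were 15.3% and 0.818% against 4.63% and 13.3% (log2 0.14, edgeR adjusted p = 0.922). Schwann-like cells had a log2 ratio of 0.33, edgeR adjusted p = 0.908.

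A shallow unnamed cluster led by the T-cell genes Camk4 and Themis held 53 and 0 cells in saline and 303 and 51 in VIVIT 2 and 3, and stayed out of the T/NK share because it was shallow and none of its leading genes was a T/NK marker. Adding it and a shallow fibroblast-like cluster gave log2 2.28 for T/NK and −1.48 for fibroblast-like cells. Without saline 2 the T/NK log2 ratio was 3.63, but saline 3 then stood alone and the error came only from VIVIT 2 and 3.

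**Figure D1:**
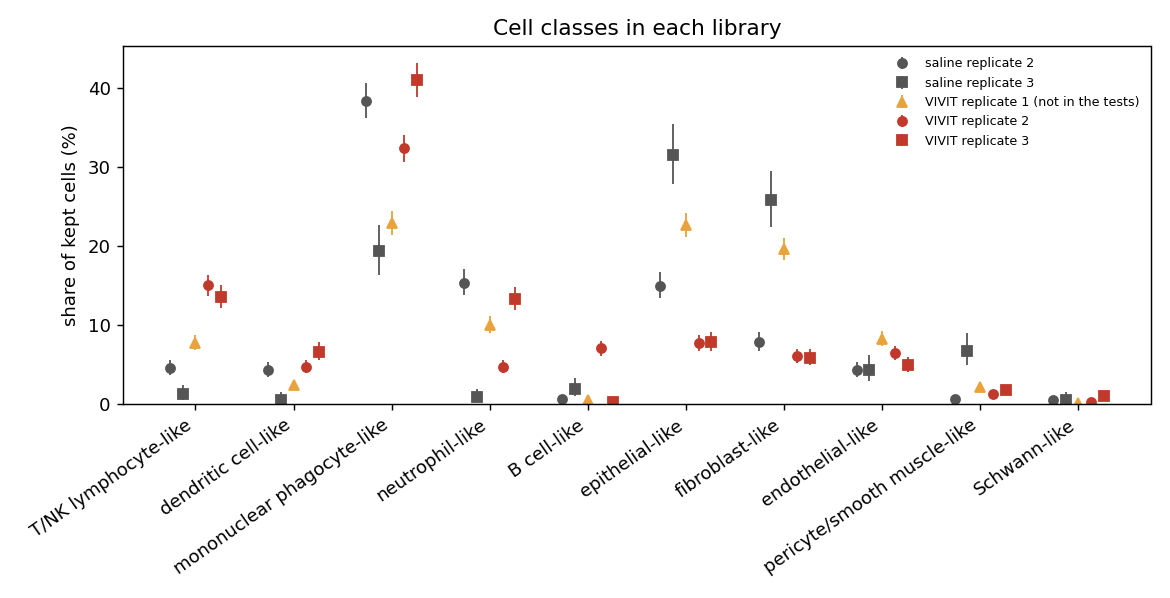
Share of kept cells (percent) in each class, 1 point per library with its 95% exact binomial interval. T/NK lymphocytes lie at 4.55% and 1.15% in saline and 14.99% and 13.5% in VIVIT 2 and 3.

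Do tumour fibroblasts lose an NFAT programme or change state? Fibroblast-like cells from VIVIT 2 and 3 leaned towards more interferon-response transcripts, among them Cxcl9, a chemokine that draws CXCR3-bearing T cells. The interferon list differed nearly as much between mixed pairs of libraries, and no single gene passed. Periostin (Postn), a matrix protein of activated fibroblasts, was higher in both VIVIT libraries than in both saline libraries, and the caveolar protein gene Cav1 was lower. The NFAT family genes and Rcan1, the usual readout of calcineurin-NFAT activity, differed little at harvest. NFAT activity soon after injection was not measured.

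Cxcl9 (ENSMUSG00000029417, GRCm38/mm10 chr5:92321347-92328079) was 29.8 and 22.96 CPM (counts scaled to the library total) in saline fibroblasts, 388 and 727 in VIVIT 2 and 3, and 114 in VIVIT 1 (log2 4.42, SE 0.46). Iigp1, an interferon-inducible GTPase, followed with 68.4 and 119 against 356 and 424 CPM (log2 2.07, SE 0.39), and Irgm1, of the same GTPase family, had log2 1.62 (SE 0.38). The interferon-induced Gbp2 (log2 0.97), the MHC class I activator Nlrc5 (1.08) and the peptide-loading chaperone Tapbp (0.56) leaned the same way. Postn (ENSMUSG00000027750, chr3:54361109-54391037) was 1279 and 711 against 2365 and 2798 CPM, with 2069 in VIVIT 1 (log2 1.40, SE 0.46). The matrix genes Thbs2 (log2 1.23), Lrrc15 (1.43), a marker of myofibroblastic tumour fibroblasts, and Col11a1 (1.02) were also higher. Cxcl12, the fibroblast chemokine linked to T-cell exclusion, was 95.8 and 84.1 against 147 and 197 CPM (log2 0.95, SE 0.28). Cav1 was 49.99 and 64.0 against 17.8 and 18.6 CPM, with 30.5 in VIVIT 1 (log2 −1.62, SE 0.27). The acute-phase gene Saa3 (log2 −1.35, SE 0.59), the actin nucleator Cobl (−3.63) and the angiopoietin-like gene Angptl7 (−5.94) were lower. Megf11, a cell-surface EGF-repeat gene, was higher (log2 1.87, SE 0.28). All these genes had an edgeR adjusted p = 1.00.

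At the level of single genes, 0 of 12904 passed in fibroblast-like cells by edgeR, with 475 at unadjusted p below 0.05. DESeq2 called 46 (23 higher, 23 lower). When a library is left out, here and in other classes, its group keeps a single library and the error comes only from the other group. Counts from such fits cannot be read as a treatment effect. The edgeR count was 1082 without saline 2, 0 without saline 3, 15 without VIVIT 2 and 1 without VIVIT 3.

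Of 32 gene lists, camera with its preset correlation called 15 higher and 2 lower in fibroblast-like cells. None held with an estimated correlation in this or any other class. The interferon list had a median log2 of 0.49 with 21 of 29 genes higher (adjusted p = 6.2e-06 by camera, adjusted p = 0.603 with an estimated correlation). Adjusted over the list alone 2 of its genes passed, and 0 over all genes. Without saline 2 the interferon response list in fibroblast-like cells had a median of 0.017 and without saline 3 one of 1.06. MHC class I genes had a median of 0.38 with 18 of 19 higher (adjusted p = 1.6e-05 by camera, adjusted p = 0.603 with an estimated correlation), and 0 passed adjusted over the list alone. With VIVIT 1 added the MHC class I presentation list in fibroblast-like cells had a median of 0.0094. Myofibroblastic markers (median 0.28, 14 of 23 higher), inflammatory fibroblast markers (0.48, 19 of 31), matrix remodelling enzymes (0.26, 21 of 30), collagens (0.36, 14 of 20) and proliferation genes (0.53, 24 of 29) were called higher by camera, each with adjusted p = 0.603 with an estimated correlation. So the myofibroblastic and the inflammatory fibroblast genes leaned the same way, but without saline 3 the myofibroblastic CAF genes list in fibroblast-like cells had a median of −0.16. The myofibroblastic median was 0.071 and the inflammatory one 0.26 in edgeR values, and with VIVIT 1 added the myofibroblastic median was 0.0046. Hypoxia and glycolysis genes, with the oxygen sensor Egln3 at log2 −2.55, had a median of −0.33 with 24 of 27 lower (adjusted p = 0.603 with an estimated correlation). Without the cells of a cluster with Saa3 among its leading genes the hypoxia and glycolysis list in fibroblast-like cells had a median of 0.015.

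Known NFAT targets were called higher in fibroblast-like cells (median 0.50, 14 of 21; adjusted p = 0.00122 by camera, adjusted p = 0.603 with an estimated correlation). Its leading genes were the lymphocyte genes Icos (log2 4.18), Ctla4 (3.11) and Fasl (2.31), which were higher together with T/NK markers. With VIVIT 1 added its median was 0.14 and it was not called (adjusted p = 0.108 by camera). Camera did not call the NFAT and calcineurin components (13 higher and 12 lower), and there the median of 0.01 and the mean of −0.098 had different signs, with the test pointing down. Nfatc1 (ENSMUSG00000033016, chr18:80606205-80713071) had log2 0.04 (SE 0.34), Nfatc2 0.31 (SE 0.58), Nfatc3 −0.12 (SE 0.30), Nfatc4 −0.12 (SE 0.37) and Rcan1 0.14 (SE 0.29). The cytokine genes Il6 (log2 −0.16), Cxcl1 (−0.12) and Ccl2 (0.22), the smooth-muscle actin gene Acta2 (−0.05) and the type I collagen gene Col1a1 (0.52, SE 0.50) changed in no test.

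Transcripts that belong to other cells moved in the same pool. Cytotoxic genes had a median log2 of 2.08 with 11 of 11 higher (adjusted p = 5.1e-09 by camera, adjusted p = 0.603 with an estimated correlation), including the granzyme gene Gzmc (2.89) and the granule gene Nkg7 (2.70). The adaptor gene Grap2 (log2 4.53) was among the genes with the smallest p. T/NK markers had a median of 1.89 with 10 of 11 higher. Epithelial identity genes, among them the claudin gene Cldn3 (−3.05) and the keratin gene Krt7 (−2.39), had a median of −1.55 with 12 of 12 lower (adjusted p = 0.603 with an estimated correlation). Mesothelial markers had a median of −2.62 with 10 of 10 lower (adjusted p = 0.380 with an estimated correlation), and 4 passed adjusted over the list alone. A cluster with Slit3, Timp3 and Saa3 among its 10 leading genes, here the Saa3 cluster, also carried 6 mesothelial markers. It supplied 39 and 99 of the 149 and 158 saline cells but 28 and 22 of the 171 and 118 in VIVIT 2 and 3, so mixture and change within cells are not fully separated here. Without that cluster the epithelial identity list in fibroblast-like cells had a median of 0.058, while Postn in fibroblast-like cells had log2 0.90 and Cxcl9 in fibroblast-like cells 4.10. The other 2 ways of splitting the 4 libraries into pairs called 11 and 9 lists. Their interferon medians of 0.39 and 0.47 were nearly as large as the 0.49 of saline against VIVIT, and their MHC class II medians were 0.15 and 0.98 against 0.72. For MHC class I they were 0.14 and 0.077 against 0.38.

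Do tumour-cell antigen presentation and epithelial state change? Epithelial-like cells of VIVIT 2 and 3 had higher MHC class II, MHC class I and interferon-response transcripts and lower transcripts of epithelial identity genes. H2-Ab1 encodes a chain of the class II molecule that presents peptides to CD4 T cells, and Psmb9 an interferon-inducible immunoproteasome subunit that shapes class I peptides. Prap1, Clca1 and Fcgbp, genes of intestinal and mucous epithelium, were low in VIVIT 2 and 3, but a few cells carried most of their transcripts in saline.

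H2-Ab1 (ENSMUSG00000073421, chr17:34257689-34269419) was 110.4 and 138 CPM in saline against 355 and 327 in VIVIT 2 and 3 (log2 1.44, SE 0.31). It was 81.5 in VIVIT 1, below both saline libraries. H2-Eb1, another class II chain, was 99.7 and 117 against 302 and 286, with 54.5 in VIVIT 1 (log2 1.42, SE 0.30), and H2-Aa had log2 1.48 (SE 0.31). Psmb9 (ENSMUSG00000096727, chr17:34181987-34187764) was 47.5 and 56.3 against 112 and 165 CPM, with 48.5 in VIVIT 1 (log2 1.40, SE 0.32). The peptide transporter Tap1 (log2 1.12), the class I genes H2-T22 (0.97) and H2-Q7 (1.47) and the GTPase genes Igtp (1.42) and Ifi47 (1.06) were higher, each with an edgeR adjusted p = 1.00. Ubd, an interferon- and TNF-induced ubiquitin-like modifier, was 13.3 and 7.05 against 72.9 and 91.2 CPM, with 13.3 in VIVIT 1 (log2 2.94, SE 0.42, edgeR adjusted p = 0.698). Slc7a11, the cystine importer that protects cells from ferroptosis, was 67.9 and 56.4 against 278 and 251 but 20.7 in VIVIT 1 (log2 2.06, SE 0.32, edgeR adjusted p = 0.698).

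Prap1 (ENSMUSG00000025467, chr7:140093395-140097200) was 107 and 96.5 CPM in saline, 5.06 and 3.81 in VIVIT 2 and 3 and 20.8 in VIVIT 1 (log2 −4.54, SE 0.35, edgeR adjusted p = 0.0621, the smallest in this class). Clca1 had log2 −6.22 (SE 0.65) and Fcgbp −6.81 (SE 0.73), both with an edgeR adjusted p = 0.183. In saline 2 and 3 the top 5 cells held 95.3% and 76.2% of the UMIs of these 3 genes. Without the top 5 cells of each library their sum was 9.28 and 35.4 CPM in saline, 1.12 and 2.21 in VIVIT 2 and 3 and 15.4 in VIVIT 1. The claudin gene Cldn7 (log2 −3.72, SE 0.60, edgeR adjusted p = 0.698), the tight-junction genes Cldn4 (−3.64) and Ocln (−1.61) and the adhesion gene Epcam (−1.47, SE 0.37) were lower. Epcam was 174 and 320.1 CPM against 101 and 76.9, with 149 in VIVIT 1. The early-response genes Klf2 (log2 −1.26), Zfp36 (−1.38) and Fos (−1.16) were lower too. Rcan1 had log2 0.46 (SE 0.28), Nfatc1 −0.01 and Nfatc2 −0.08. The genes given here without their own value, H2-Ab1 and Epcam among them, had an edgeR adjusted p = 1.00.

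By edgeR 0 of 13161 genes passed in epithelial-like cells, with 330 at unadjusted p below 0.05, and DESeq2 called 30 (10 higher, 20 lower). The edgeR count was 291 without saline 2, 6 without saline 3, 59 without VIVIT 2 and 47 without VIVIT 3. With at most 10% mitochondrial UMIs 1 gene passed.

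Camera called 13 of 32 lists, 10 higher and 3 lower. MHC class II genes had a median log2 of 1.34 with 12 of 12 higher (adjusted p = 7.4e-23 by camera, adjusted p = 0.193 with an estimated correlation), and 8 genes passed adjusted over the list alone against 0 over all genes. Interferon-response genes had a median of 0.87 with 28 of 31 higher (adjusted p = 5.5e-21 by camera, adjusted p = 0.193 with an estimated correlation). MHC class I genes had a median of 0.81 with 18 of 19 higher (adjusted p = 3.2e-21 by camera, adjusted p = 0.212 with an estimated correlation). With VIVIT 1 added these medians were 0.67 for MHC class II, 0.45 for interferon-response and 0.47 for MHC class I genes. VIVIT 1 itself, of another chemistry, did not share the pattern. Its H2-Aa, H2-Ab1, H2-Eb1 and Cd74 summed to 371 CPM, below the 679 and 704 of saline 2 and 3. Its H2-K1, H2-D1, B2m, Psmb9 and Tap1 summed to 2834 CPM, below 4283 and 3251. Epithelial identity genes had a median of −0.49 with 22 of 22 lower (adjusted p = 1.3e-11 by camera, adjusted p = 0.212 with an estimated correlation), and 1 passed adjusted over the list alone. Dissociation and immediate early genes had a median of −0.34 with 23 of 28 lower (adjusted p = 4.0e-08 by camera, adjusted p = 0.193 with an estimated correlation). This list also covers the response to tissue dissociation, so handling of the tumours and treatment cannot be told apart in it. Collagens, which belong to fibroblasts, had a median of −0.35 with 15 of 20 lower (adjusted p = 0.000146 by camera, adjusted p = 0.212 with an estimated correlation). Phagocyte markers had a median of 1.58 with 15 of 16 higher (adjusted p = 0.350 with an estimated correlation), and the myeloid cytokine genes Il1b (log2 2.50) and Ccl6 (1.87) were higher in the same pool. Dendritic cell markers, also of a class II-rich cell type, had a median of 0.62 with 6 of 7 higher (adjusted p = 0.350 with an estimated correlation). Removing the highest 5% of doublet scores took Ccl6 in epithelial-like cells to 0.19 but left the MHC class II presentation list in epithelial-like cells at 1.32. Median UMIs per epithelial-like cell were 4720.5 and 5181 in saline against 15304.5 and 28196.5 in VIVIT 2 and 3. So this class is not matched for depth. Without its shallow cluster the medians were 47832 and 40016 against 58126.5 and 57215, closer but still lower in saline. The other 2 splits of the libraries called 9 and 6 lists, with interferon medians of 0.32 and 0.08 and class II medians of −0.09 and −0.07.

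**Figure D2:**
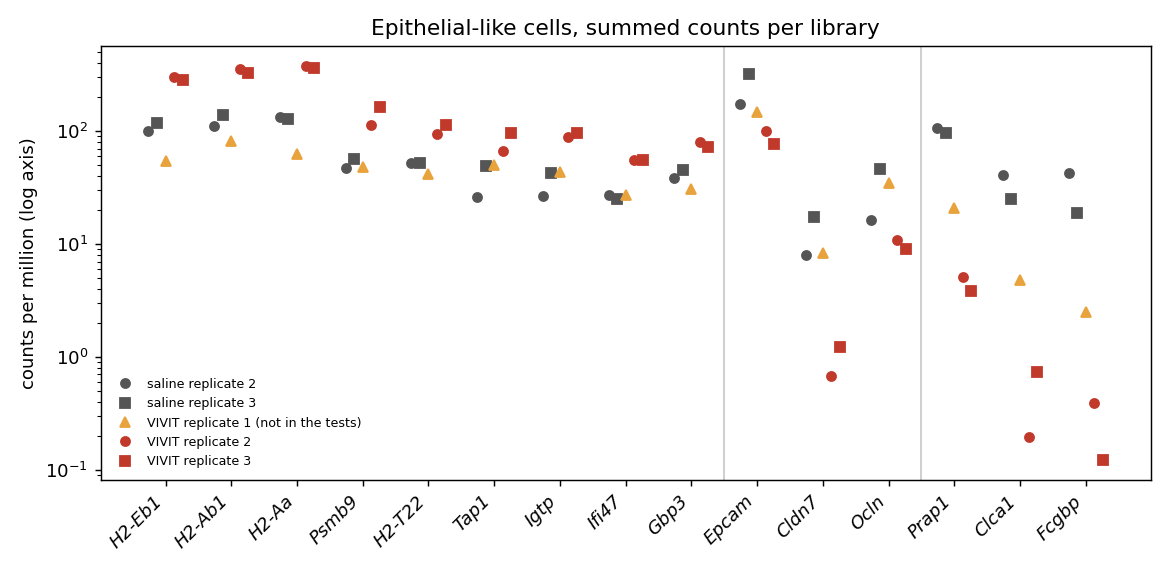
Log CPM of named genes in epithelial-like cells, 1 point per library. H2-Ab1 lies at 110.4 and 138 CPM in saline and 355 and 327 in VIVIT 2 and 3, with VIVIT 1 at 81.5.

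Do tumour phagocytes change with the VIVIT injection? Phagocyte-like cells of VIVIT 2 and 3 had more MHC class I and interferon-response transcripts, and Dnase1l3, a secreted nuclease of macrophages and dendritic cells, was higher. Cd163, the haemoglobin scavenger receptor of alternatively activated macrophages, was lower. No single gene passed.

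Dnase1l3 (ENSMUSG00000025279, chr14:7964533-7994573) was 28.8 and 28.9 CPM in saline, 94.4 and 102 in VIVIT 2 and 3 and 56.4 in VIVIT 1 (log2 1.80, SE 0.23). The monocyte genes Ly6i (log2 2.39, SE 0.36) and Ly6c2 (1.62, SE 0.31) were higher. Cd163 (ENSMUSG00000008845, chr6:124304656-124330527) was 24.0 and 14.5 against 5.05 and 1.89, with 7.16 in VIVIT 1 (log2 −2.52, SE 0.56). The leukotriene synthase gene Ltc4s (log2 −1.54) and the growth-factor gene Bmp2 (−1.50) were lower. Among interferon genes Irgm1 had log2 1.28 (SE 0.28), Igtp 1.22 and Cxcl9 1.14 (SE 0.31). Rcan1 had log2 0.34 (SE 0.55), Nfatc1 −0.37 (SE 0.43), Nfatc2 −0.95 (SE 0.69) and Nfatc3 −0.16. All had an edgeR adjusted p = 1.00.

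By edgeR 0 of 11919 genes passed in phagocyte-like cells, with 324 at unadjusted p below 0.05, and DESeq2 called 2, both higher. The edgeR count was 2401 without saline 2, 304 without saline 3, 3 without VIVIT 2 and 13 without VIVIT 3. Saline 3 gave only 0.968 M UMIs from 118 phagocyte-like cells, and 1 and 5 of them lay in the Cxcl3-led and Apoe-led clusters that held 247 and 246 cells of saline 2.

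Camera called 13 of 32 lists, all higher. MHC class I genes had a median log2 of 0.53 with 19 of 19 higher (adjusted p = 1.6e-11 by camera, adjusted p = 0.348 with an estimated correlation). Interferon-response genes had a median of 0.33 with 24 of 30 higher (adjusted p = 5.4e-05 by camera, adjusted p = 0.348 with an estimated correlation). MHC class II genes had a median of 0.56 with 10 of 14 higher, H2-Ab1 among them at 0.72 (adjusted p = 0.000307 by camera, adjusted p = 0.483 with an estimated correlation). Known NFAT targets had a median of 0.34 with 13 of 21 higher (adjusted p = 0.0386 by camera, adjusted p = 0.483 with an estimated correlation). Without saline 3 the known NFAT target genes list in mononuclear phagocyte-like cells had a median of −0.041, and in edgeR values of all 4 libraries its median was 0.088. Lipid-associated macrophage genes had a median of 0.32 with 14 of 20 higher although the osteopontin gene Spp1 had log2 −0.49 (adjusted p = 0.0307 by camera, adjusted p = 0.830 with an estimated correlation). Their median was 0.14 in edgeR values. Lymphocyte transcripts moved beside them: cytotoxic genes had a median of 1.26 with 9 of 11 higher (adjusted p = 2.7e-06 by camera, adjusted p = 0.348 with an estimated correlation). Inhibitory receptor genes, with Pdcd1 at log2 2.29, had a median of 0.80 with 12 of 13 higher (adjusted p = 0.000307 by camera, adjusted p = 0.348 with an estimated correlation), and T/NK markers a median of 1.09 with 7 of 7 higher. In each of these lists 0 genes passed adjusted over the list alone. With VIVIT 1 added the medians were 0.16 for MHC class I, 0.048 for interferon-response and 0.21 for MHC class II genes. Of these only MHC class I was still called (adjusted p = 0.0275, 0.305 and 0.295 by camera). The other 2 splits called 11 and 10 lists.

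Do tumour endothelial cells change? Endothelial-like cells of VIVIT libraries carried more class II transcripts, led by Cd74, the invariant chain, and fewer transcripts of dividing cells. Lyz2, the lysozyme of phagocytes, was higher in the same cells by a similar amount, so the class II signal came together with phagocyte markers. Saline 3 supplied only 26 endothelial-like cells and 0.237 M UMIs.

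Cd74 (ENSMUSG00000024610, chr18:60803848-60812652) was 43.0 and 33.8 CPM in saline, 258 and 246 in VIVIT 2 and 3 and 65.1 in VIVIT 1 (log2 2.71, SE 0.39, edgeR adjusted p = 0.906). H2-Ab1 had log2 2.92 (SE 0.60). Lyz2 had log2 2.74 (SE 0.40, edgeR adjusted p = 0.906), and the phagocyte genes Ctss (3.20), C1qb (3.26) and Mrc1 (2.36) were higher as well. Removing the highest 5% of doublet scores took Lyz2 in endothelial-like cells to 0.85 and Cd74 in endothelial-like cells to 1.96. The mitotic genes Cenpf (log2 −2.61), Ccnb2 (−1.90) and Ube2c (−2.42), the histone gene Hist1h2ae (−2.39) and the keratin gene Krt8 (−2.11) were lower. By edgeR 0 of 9641 genes passed, with 238 at unadjusted p below 0.05, and DESeq2 called 4, all higher. The edgeR count was 54 without saline 2, 1 without saline 3, 6 without VIVIT 2 and 2 without VIVIT 3.

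Camera called 12 of 30 lists in endothelial-like cells, 10 higher and 2 lower. MHC class II genes had a median log2 of 2.50 with 8 of 8 higher (adjusted p = 2.0e-14 by camera, adjusted p = 0.504 with an estimated correlation), and 7 passed adjusted over the list alone against 0 over all genes. MHC class I genes (median 0.46, 16 of 19 higher) and interferon-response genes (0.29, 21 of 27 higher), including Rsad2 at log2 1.99, were called (adjusted p = 0.000243 by camera and adjusted p = 0.439 with an estimated correlation for both). With VIVIT 1 added their medians were 0.014 and 0.19 and neither was called, while MHC class II stayed at 1.88. Proliferation genes had a median of −0.84 with 23 of 26 lower (adjusted p = 2.1e-11 by camera, adjusted p = 0.439 with an estimated correlation). Epithelial markers were lower with them (median −0.95, 4 of 5 lower, adjusted p = 0.221 with an estimated correlation), as were epithelial identity genes (−0.62, 5 of 6 lower, adjusted p = 0.504 with an estimated correlation). Phagocyte markers had a median of 1.80 with 11 of 12 higher (adjusted p = 0.117 with an estimated correlation), and 7 passed adjusted over the list alone. The other 2 splits called 2 and 7 lists.

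What changes in the tumour as a whole? With all kept cells summed, transcripts of T cells and of antigen presentation were higher in VIVIT 2 and 3 and epithelial transcripts lower. Shares of the classes and changes within them are not separated in this sum. Prf1, the pore-forming protein of killer lymphocytes, stood for the first group and Epcam, the epithelial adhesion molecule, for the second.

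Prf1 (ENSMUSG00000037202, chr10:61297833-61304680) was 1.11 and 0.360 CPM in saline, 5.97 and 6.77 in VIVIT 2 and 3 and 2.69 in VIVIT 1 (log2 3.04, SE 0.66). The checkpoint genes Ctla4 (log2 2.71) and Tigit (2.22) and the T-cell transcription factor gene Bcl11b (1.75) were higher, as were Psmb9 (1.22, SE 0.24) and Tap1 (1.17). All these genes had an edgeR adjusted p = 0.905. Epcam had log2 −1.85 and Cldn7 −3.76, while Prap1 had −4.996 (SE 0.25), the smallest edgeR adjusted p of this comparison at 0.236. The acinar enzyme genes Prss2 (log2 −3.87) and Ctrb1 (−4.80) were lower, but both changed sign when VIVIT 1 was added (0.34 and 0.98). By edgeR 0 of 16980 genes passed, with 686 at unadjusted p below 0.05, and DESeq2 called 77 (28 higher, 49 lower). The edgeR count was 4529 without saline 2, 25 without saline 3, 0 without VIVIT 2 and 0 without VIVIT 3.

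Camera called 17 of 34 lists in the summed cells, 13 higher and 4 lower, and the smallest adjusted p = 0.790 with an estimated correlation, which the gene lists named next share. Cytotoxic genes had a median log2 of 2.75 (19 of 21 higher), regulatory T-cell genes 2.25 (14 of 16), MHC class II genes 1.51 (14 of 14), inhibitory receptors 1.27 (16 of 17), MHC class I genes 0.71 (18 of 19) and interferon-response genes 0.62 (25 of 31). With VIVIT 1 added the interferon median was 0.13, MHC class I 0.37 and MHC class II 0.76. For MHC class I 7 genes passed adjusted over the list alone against 0 over all genes. Angiogenesis genes, with the von Willebrand factor gene Vwf at log2 1.31, had a median of 0.53 (18 of 22 higher). Epithelial identity genes had a median of −1.03 with 23 of 23 lower and acinar genes −2.57 with 7 of 7 lower. T/NK markers had a median of 3.08 (17 of 18 higher), mesothelial markers −1.77 (10 of 10 lower) and plasma-cell markers −2.67 (7 of 7 lower). The other 2 splits of the libraries called 18 and 16 lists, as many as the comparison of saline with VIVIT.

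Does VIVIT act differently on fibroblasts and on phagocytes? In a direct test of the difference between both classes, the VIVIT effect on proliferation genes leaned further up in fibroblast-like than in phagocyte-like cells. The effect on epithelial identity genes leaned further down in fibroblast-like cells, a class that includes the Saa3 cluster with its 6 mesothelial markers. By limma 0 of 10818 genes passed, with 370 at unadjusted p below 0.05 and a smallest adjusted p of 0.929, and the count was 297 without saline 2. Proliferation genes had a median difference of 0.48 log2 (adjusted p = 0.000186 by camera, adjusted p = 0.846 with an estimated correlation). Epithelial identity genes had a median difference of −1.95 (adjusted p = 0.000838 by camera, adjusted p = 0.846 with an estimated correlation). The difference was not tested without the Saa3 cluster, but without those cells the epithelial identity list in fibroblast-like cells had a median of 0.058.

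**Figure D3:**
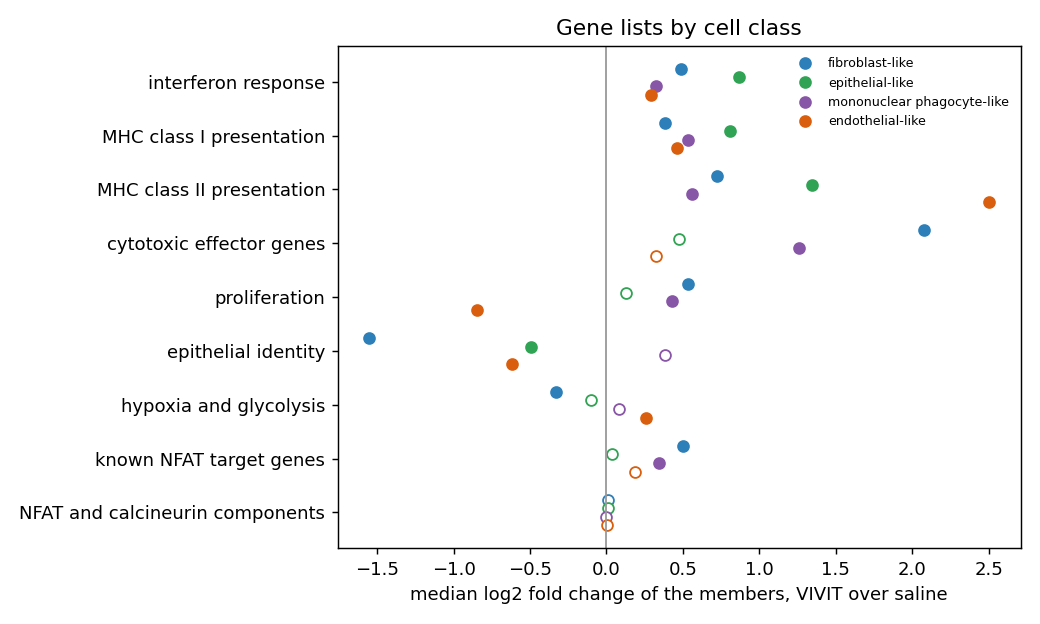
Median log2 ratio, VIVIT against saline, of each gene list (axis) in each cell class, with filled points for lists called by camera with the preset correlation and open points for the others. MHC class II has medians of 1.34 in epithelial-like and 2.50 in endothelial-like cells, and no filled point holds with an estimated correlation.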

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

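The T/NK share tests and the endothelial class II test below were chosen only after the result was seen, and the other tests were written before their values were known.

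The T/NK share in VIVIT 1 was 7.69%, above both saline libraries, and stands out because this library took no part in the 4-library tests. The endothelial-like share in VIVIT 1 was 8.22%, above both saline libraries for the same reason, though its chemistry differs from theirs. Proliferation genes had a fibroblast-like minus phagocyte-like difference of 0.48 and epithelial identity genes one of −1.95. Both stand out because the difference itself was called by camera, and neither held with an estimated correlation (adjusted p = 0.846). Without the Saa3 cluster the epithelial identity list in fibroblast-like cells had a median of 0.058, but the −1.95 itself was not tested without it.

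More T/NK lymphocytes were found in every VIVIT library. Few intact cells in saline 3 may contribute: the log2 ratio without it was 1.65, but its SE of 0.298 comes only from VIVIT 2 and 3 and the edgeR adjusted p was 0.358, so this stays open. Loss of lymphocytes to the cell filters is not excluded. T-cell receptor complex genes over all barcodes were 2.78 times higher in the lower of VIVIT 2 and 3 than in the higher saline library. VIVIT 1 was at 60.1 CPM against 52.9 in saline 2. But kept cells held 34.4 of 34.8 M UMIs in saline 2 and 13.9 of 14.5 M in saline 3. Such a sum can therefore hardly show lymphocytes lost with few UMIs. Fewer epithelial-like cells in the total cannot be told apart from more lymphocytes, with log2 2.11 (SE 1.16) among the other cells. Entry or growth of lymphocytes under VIVIT remains a hypothesis that counting labelled T cells in sections would test.

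Interferon and antigen presentation genes were higher in several classes. RNA of the average phagocyte was estimated to account for 7.001% of fibroblast Cxcl9, 20.2% of epithelial class II and 2.04% of epithelial class I transcripts. These are the higher values of VIVIT 2 and 3, and they argue against average phagocyte RNA as the main source there. RNA from a phagocyte subset rich in these transcripts, or from dendritic cells, was not estimated. For endothelial class II transcripts the estimate for average phagocyte RNA was 63.1% in the lower of VIVIT 2 and 3, so that signal fits carried-over RNA. But removing the highest 5% of doublet scores took Lyz2 in endothelial-like cells to 0.85 and left Cd74 in endothelial-like cells at 1.96. Low quality of saline 3 alone does not account for the higher epithelial interferon median, which was 0.88 without that library against 0.87 with it. Saline 2 then stood alone, so the 0.88 carries no spread between saline libraries. VIVIT 1 had a T/NK share above both saline libraries, yet its summed epithelial class I and class II transcripts lay below both. Its chemistry differs, so this single library does not settle the matter. Interferon from more T cells under VIVIT remains a hypothesis that blocking interferon gamma during treatment would test.

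Prap1, Clca1 and Fcgbp were lower in epithelial-like cells of VIVIT 2 and 3. The Pkhd1-led cluster is not the source, since the smallest of the 3 drops was still −4.57 without it, but it held only 0 and 8 saline cells, so host duct cells elsewhere stay open. A few cells fit as a large part, because 5 cells held 76.2% of these UMIs in the saline library where they held least. Without the top 5 cells of each library the 3 genes were 9.28 and 35.4 CPM in saline, 1.12 and 2.21 in VIVIT 2 and 3 and 15.4 in VIVIT 1, so what remains does not separate all VIVIT from all saline libraries. Whether such cells are lost under VIVIT or were merely sampled in saline may not be settled from 2 libraries.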

How the results depend on the processing

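Among results other than gene counts, list counts and shares, 2405 alternative values stayed the same, 271 were stronger, 136 weaker and 60 reversed. Among the counts and shares 221 stayed the same, 48 moved and 9 reversed. The cause was not tested for any of them. The alternatives were not run on 4 libraries for neutrophil-like, T/NK, dendritic, B and pericyte-like genes, where a library had fewer than 20 cells. Saline 3 gave the fewest UMIs in the phagocyte-like (0.968 M) and endothelial-like (0.237 M) classes, which limits what can be found there.

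Genes changed numbered 46 in fibroblast-like, 30 in epithelial-like, 2 in mononuclear phagocyte-like and 4 in endothelial-like cells and 77 in all cells summed with DESeq2. With no filter on low counts they numbered 352, 232, 114, 71 and 1. With at most 10% mitochondrial UMIs genes changed in epithelial-like cells numbered 1, and without the Pkhd1-led cluster, an alternative chosen after seeing the data, 1. Leaving out each library gave from 0 to 1082 genes changed in fibroblast-like cells, 6 to 291 in epithelial-like, 3 to 2401 in mononuclear phagocyte-like, 1 to 54 in endothelial-like cells and 0 to 4529 in all cells summed. Each highest count came without saline 2, where saline 3 stood alone and the error came only from VIVIT 2 and 3. The difference of the VIVIT effect between fibroblast-like and mononuclear phagocyte-like cells gave 0 to 297 genes.

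The replicate number pairs only 2 libraries per group and nothing beyond the number links them, so pairing is not established. Profiles of the same number correlated at 0.0529 in fibroblast-like, 0.192 in epithelial-like, −0.108 in mononuclear phagocyte-like, −0.0230 in endothelial-like cells and 0.0414 in all cells. With the replicate block 20 genes changed in epithelial-like and 12 in endothelial-like cells, and 0 in the others. Crossing the block, chosen after seeing the data, gave 1 gene changed in mononuclear phagocyte-like cells. With the block Nfatc1 (−0.012), Cxcl1 (0.65) and Acta2 (0.056) in fibroblast-like cells and Nfatc1 (0.0022) and Nfatc2 (0.039) in epithelial-like cells changed sign, and the share of Schwann-like cells was −0.045.

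These counts are of the gene lists, without the marker lists. Gene lists called numbered 0 in fibroblast-like, 0 in epithelial-like, 0 in mononuclear phagocyte-like and 0 in endothelial-like cells and 0 in all cells with camera and an estimated correlation. With fry they numbered 0, 0, 0, 0 and 0. With all 5 libraries 10 lists were called in fibroblast-like cells, 4 in endothelial-like cells and 11 in all cells. In endothelial-like cells 7 were called with at most 10% mitochondrial UMIs and 6 with the highest 5% of doublet scores removed, chosen after seeing the data.

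Cell class shares without each library ranged from 1.65 to 3.63 for T/NK lymphocyte-like, −2.03 to −0.955 for epithelial-like, −2.13 to −0.40 for fibroblast-like, 0.41 to 3.50 for dendritic cell-like, −2.46 to 2.77 for B cell-like, −0.07 to 0.93 for mononuclear phagocyte-like, −0.81 to 3.44 for neutrophil-like, −2.22 to 1.45 for pericyte/smooth muscle-like and −1.07 to 1.04 for Schwann-like cells. The Schwann-like share was −0.14 with all 5 libraries and the neutrophil-like share −0.0020 among cells other than epithelial-like.

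In fibroblast-like cells all 5 libraries reversed Nfatc3 (0.15), Nfatc4 (0.38) and Ccl2 (−0.24). Leaving out the Saa3 cluster, chosen after seeing the data, reversed Egln3 (0.22), Il6 (0.034), Acta2 (0.068) and the hypoxia and glycolysis list (0.015). Leaving out each library gave ranges of −0.41 to 0.39 for Nfatc1, −0.55 to 0.85 for Nfatc2, −0.36 to 0.20 for Nfatc3, −0.50 to 0.43 for Nfatc4, −0.16 to 0.39 for Rcan1, −0.63 to 0.60 for Il6, −0.97 to 2.30 for Cxcl1 in fibroblast-like cells, −0.58 to 2.27 for Ccl2 and −0.53 to 0.70 for Acta2. The inflammatory CAF genes list ranged from 0.030 to 0.89 and the chemokines and cytokines list in fibroblast-like cells from −0.12 to 1.501.

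In epithelial-like cells Nfatc1 was 0.016 with no filter on low counts. With at most 10% mitochondrial UMIs Nfatc1, Nfatc2 and Nfatc3 were 0.034, 0.041 and −0.059, and at Leiden resolution 0.5 they were 0.050, 0.026 and −0.067. With doublets kept Nfatc1 was 0.0087 and Nfatc3 −0.032. Alternatives chosen after seeing the data put Nfatc3 in epithelial-like cells at −0.0010 and Slc7a8 at −0.28 with the highest 5% of doublet scores removed, and Nfatc3 at −0.020 without the Pkhd1-led cluster and −0.0013 with shallow clusters left out. Leaving out each library gave −0.27 to 0.30 for Nfatc1, −0.56 to 0.63 for Nfatc2 and −0.093 to 0.097 for Nfatc3. The chemokines and cytokines list in epithelial-like cells was −0.32 with all 5 libraries and ranged from −0.43 to 1.41.

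The ranges without each library were −0.24 to 1.69 for Rcan1, −0.91 to 0.30 for Nfatc1, −1.71 to 0.21 for Nfatc2 and −0.43 to 0.12 for Nfatc3 in mononuclear phagocyte-like cells. The known NFAT target genes list ranged from −0.041 to 0.45 and the lipid-associated macrophage genes list from −0.20 to 0.81. They were −1.07 to 0.72 for Rcan1, −0.79 to 0.24 for Nfatc1, −0.70 to 0.20 for Nfatc4 and −4.43 to 0.14 for Nfatc2 in endothelial-like cells. In all cells Prss2 was 0.34 and Ctrb1 0.98 with all 5 libraries.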

Other observations

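Transcripts of the Y chromosome separated the epithelial-like clusters from the rest of the tumour. They summed to 14.7, 7.41 and 7.47 CPM in both large epithelial-like clusters and in an unnamed cluster, against 540 CPM in the small Pkhd1-led epithelial-like cluster. As a hypothesis, the large clusters are grafted KPC cells without Y expression and the Pkhd1-led cells are host duct. Comparing strain variants in the reads of each cluster with those of cultured KPC cells and of host pancreas would test this.

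NFAT family members were unevenly spread over the cell types. The values are means ± SD over the tested libraries with enough cells (n = 3 for neutrophil-like, T/NK and pericyte-like, n = 4 for the others). Nfatc1 was 163 ± 17.6 CPM in neutrophil-like cells, 140.0 ± 19.4 in T/NK lymphocytes, 107 ± 23.9 in fibroblast-like, 77.8 ± 28.5 in endothelial-like and 42.1 ± 10.2 in epithelial-like cells. Nfatc3 was highest in T/NK lymphocytes (284 ± 27.2 CPM) and Nfatc4 in pericyte-like (49.3 ± 21.6) and fibroblast-like cells (24.6 ± 6.45). Rcan1, in contrast, was highest in endothelial-like (156 ± 82.1) and fibroblast-like cells (119 ± 20.1). It was 21.4 ± 6.86 CPM in neutrophil-like cells and 8.42 in T/NK lymphocytes, below the 37.1 ± 7.29 of epithelial-like cells. As a hypothesis that rests on Nfatc1 levels and not on Rcan1, neutrophils and T cells are the main direct targets of an injected NFAT inhibitor. Staining for nuclear NFATc1 by cell type in treated tumours would test this.

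Nr4a1 is 1 member of the list of known NFAT targets. Among T/NK lymphocytes it was 148 CPM in saline 2 and 58.7 and 64.0 in VIVIT 2 and 3, but 167 in VIVIT 1. Other members of that list differed in direction. Nr4a3 leaned the same way, by less in VIVIT 2 and 3, at 358 against 279 and 327, with 725 in VIVIT 1. Egr2 was 4.59 (3 UMIs) against 2.51 and 0.914, with 2.85 in VIVIT 1. Rcan1 went the other way at 4.59 (3 UMIs) against 8.78 and 11.9, with 19.0 in VIVIT 1. All known NFAT targets summed to 4911 against 4503 and 5619, with 6519 in VIVIT 1. In neutrophil-like cells, by contrast, they summed to 79681 CPM in saline 2 against 37214 and 39999 in VIVIT 2 and 3, with 20446 in VIVIT 1. Chemokines and cytokines, a list that shares Tnf and Cxcl2 with the NFAT targets, fell alike there (115930 against 58261 and 58620). So did inflammatory and suppressive neutrophil genes (130373 against 66752 and 70686.5), while interferon-response genes were higher (1203 against 2558 and 1754). The lower sum was therefore not particular to NFAT targets. In T/NK lymphocytes Gzmb (208 against 222 and 220) and Ifng (47.5 against 54.3 and 55.3) were close in saline 2 and VIVIT 2 and 3. Both were lower in VIVIT 1 (88.3 and 22.8). Pdcd1 was 547 against 588 and 608, with 527 in VIVIT 1. Prf1 was higher (53.6 against 79.4 and 88.2, with 73.1 in VIVIT 1). Gzma (398 against 110.4 and 64.0) and Gzme (59.7 against 4.71 and 8.69) were lower. They were not the 2 lower genes of the run below, which were Cxcl10 (log2 −4.02) and Il10 (−3.73). These are levels from 1 saline library, looked at after seeing the data. An edgeR run with that library against VIVIT 2 and 3, whose error comes only from the VIVIT pair, called 1 gene higher and 2 lower of 9872, and 0 with VIVIT 1 added. The same run in neutrophil-like cells called 72 higher and 85 lower of 6039, and again 0 with VIVIT 1 added.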
